A study of Oryza sativa with 8 samples.

How the data were processed

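Root RNA of the rice cultivar IR64 was hybridised to Affymetrix rice arrays, 1 array per sample, and 8 arrays were used here. Per the labels, the plants either carried OsPSTOL1 behind the constitutive 35S promoter (transgenic, T) or were null segregants without it (NT). They grew in pots in a greenhouse, in P-deficient soil or in P-fertilised soil. Each of the 4 groups holds 2 arrays that the labels call biological replicates. Per the labels' protocols, total root RNA was taken with Trizol and treated with DNase. Roots in P-deficient soil were collected at heading and roots in P-fertilised soil at mid-tillering, so soil and stage changed together and cannot be told apart.

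The deposited values are intensity values on a linear scale, 1 per probe set and array, for 57381 probe sets. GCOS was used, per the submitters' processing notes, and its version and settings are not given in the sources used here. From the values themselves, the mean of each deposited array after trimming 2 percent at each end was 100.01 to 100.02, so the authors' intensity values had been scaled to a common level before deposit. Median signals ran from 14.1 to 18.3. No detection calls or probe-level values were used, and no background correction or normalization was added in the main setting. The number of arrays limits the precision.

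Values were analysed as log2(value + 32), so every log2 change is on the log2(value + pseudocount) scale, which understates the change of low signals. The 187 control probe sets were left out (123 with AFFX names and 64 reporter probe sets). The 40 percent of probe sets with the lowest mean log2 value were left out too, which set the limit at 5.39 and kept 34316 probe sets. Group means of the 4 groups were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), with 4 residual degrees of freedom, a median of 4.28 prior degrees of freedom and Benjamini-Hochberg adjustment at 0.05. The comparisons were T minus NT over both soils, in P-deficient soil and in P-fertilised soil, the difference of these effects between soils (the interaction), and P-deficient minus P-fertilised soil over both genotypes and in each. With 2 arrays per group, p-values rest on the spread between these arrays, pooled over the 4 groups and drawn toward that of other probe sets. Replicates lay further apart in P-deficient soil (SD of the log2 difference 0.372 in T and 0.423 in NT) than in P-fertilised soil (0.282 and 0.275). A comparison within a soil therefore does not use the spread of that soil alone. The groups, tests, filter, pseudocount, descriptions behind the gene lists, rule for named genes and the alternative settings were chosen before the data were examined.

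Genes were named through the platform annotation that pairs probe sets with genes, with names from a RefSeq gene table of assembly ASM3414082v1. That table served for names only, so no coordinates are given. Of the probe sets that are not controls, 22436 had 1 gene, 95 had several and 34663 were not listed with a gene. All 22436 matched the RefSeq table, covering 17905 genes, of which 2443 had a name from the literature. No probe set was named as PSTOL1 or SQD2, so neither is reported. The annotation holds names but no descriptions of function. The 30 gene lists, fixed as descriptions and locus identifiers, were therefore matched through patterns of gene names written after the annotation was seen and before any test was run. In the same way, the rule's condition on descriptions was read as having a literature name. The name patterns also took in genes outside the fixed descriptions, such as PETE and LFNR1 in the photosynthesis list and Nramp1 in the iron acquisition list.

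Lists were tested with limma's camera at a preset correlation of 0.01, over 16166 genes with 1 probe set each (that with the highest mean), with Benjamini-Hochberg adjustment over the 24 lists that had at least 5 genes. The other 6 had too few. An estimated correlation and fry served as further readings. Fry tests whether a list's genes changed in a shared direction, without setting them against the other genes. Reporter probe sets were compared between 4 T and 4 NT arrays with a two-sided exact permutation test, whose smallest possible p is 0.0286. The ratio of the 3-prime to the 5-prime control probe set of GAPDH and of actin was taken per array as a sign of RNA integrity.

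The named genes are, for soil over both genotypes and for T against NT over both soils, up to 12 each way with the largest change among those past the threshold, whose groups do not overlap in either stratum, with exactly 1 gene and a name. For the other comparisons 5 each way were taken. Where fewer passed, those with the smallest p were added up to 5 each way and are said not to pass. Up to 4 members with the smallest p were taken from each list described, along with fixed phosphate genes. Any other item is said to have been chosen after its values were seen.

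The alternatives were a pseudocount of 1 or 100, quantile normalization, median centring, no filter, a filter on the lowest 60 percent, eBayes without the trend, the replicate number as a block, only the arrays of the soil or genotype compared, and each array left out in turn. Chosen after seeing the data were a covariate for the GAPDH ratio, a crossed pairing of replicates in P-deficient soil, the soil comparison without both T arrays of P-deficient soil, additive models and limma on the reporters. The procedure was tested on simulated data of 34316 probe sets, 200 of them changed. Over both soils, T against NT recovered 94 of 100 changes of 2-fold and 100 of 100 of 4-fold, with 9 false calls. In P-deficient soil it recovered 71 and 97 of 100, with 6 false calls, and between soils 91 and 99 of 100, with 13 false calls. The 2-fold and 4-fold sizes are on the log2(value + pseudocount) scale, so low signals must change by more than that to reach them. The rates describe the simulated data only. Whether they hold for real arrays, whose replicate spread differed between soils, was not tested, so they do not give the share of real changes found. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.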

Results

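Roots of rice plants were profiled on arrays to ask how the protein kinase gene OsPSTOL1, tied to tolerance of phosphorus (P) deficiency, changes root transcripts when it is expressed constantly. Transgenic plants (T) and null segregants without the transgene (NT) of the cultivar IR64 were sampled in P-deficient and in P-fertilised soil, with 2 arrays in each of the 4 groups. Plants in P-deficient soil were at heading and plants in P-fertilised soil at mid-tillering, so every difference between soils given here joins soil and growth stage. The summed intensity per array ran from 8060018 to 8802152. Across probe sets, which are not independent replicates, log2 signals of replicate arrays correlated at 0.964 to 0.984. Those of different genotypes in the same soil correlated at 0.951 to 0.987 and those of different soils at 0.804 to 0.83. In P-deficient soil T replicate 2 and NT replicate 1 (0.978) lay above the replicates (0.973 in T and 0.964 in NT). In P-fertilised soil replicate 2 of T and of NT (0.987) also lay above the replicates (0.983 and 0.984). The first principal component held 80.3% of the variance and parted the soils, and the second held 7.1%, with scores of 51.83 and 9.21 on the T arrays and -30.26 and -32.15 on the NT arrays of P-deficient soil.

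The transgene itself was not read by a named probe set. Reporter probe sets for genes used in transformation constructs were compared between T and NT arrays, without knowing which of these genes, if any, the construct of the T plants holds. The reporter probe set RPTR-Os-K01193-1_at read 3348.2 and 3393.7 on the T arrays of P-fertilised soil and 345.3 and 1887.6 on those of P-deficient soil, against 185.4, 198, 176.7 and 10.8 on the NT arrays. It was higher on all 4 T arrays than on any NT array, by 3.55 on the log2 scale, at an exact permutation p = 0.0286, the smallest that 4 against 4 arrays can give (adjusted p = 0.366 over 64 reporter probe sets). In all, 5 reporter probe sets had an unadjusted p under 0.05 in the exact test, and 0 passed after adjustment. Over 64 probe sets this test could pass only if most of them reached its smallest p, so its 0 was nearly fixed in advance. In limma 0 passed too, and RPTR-Os-K01193-1_at had an adjusted p of 0.134. The other reporter probe sets read 51.4 or less on every array.

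Some signs of RNA integrity set the T arrays of P-deficient soil apart, replicate 1 the most. GAPDH, a glycolytic enzyme whose control probe sets read both ends of its transcript, had a 3-prime to 5-prime ratio of 198 and 3.05 on the T arrays of P-deficient soil and 1.15 and 1.21 on the NT arrays of that soil. In P-fertilised soil the ratio was 2.16 and 1.55 in T and 1.61 and 1.94 in NT. The 5-prime probe set of actin, a cytoskeletal protein, read 4.6 and 48.3 in T and 187.6 and 164.2 in NT in P-deficient soil, against 353.5 to 464.9 in P-fertilised soil. The cyclophilin ratio was 8.81 and 2.84 in T and 1.62 and 3.20 in NT in P-deficient soil, so T replicate 2 lay below NT replicate 2, and the ubiquitin ratio of 0.957 and 0.727 in T and 0.749 and 0.721 in NT differed little.

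**Figure D1:**
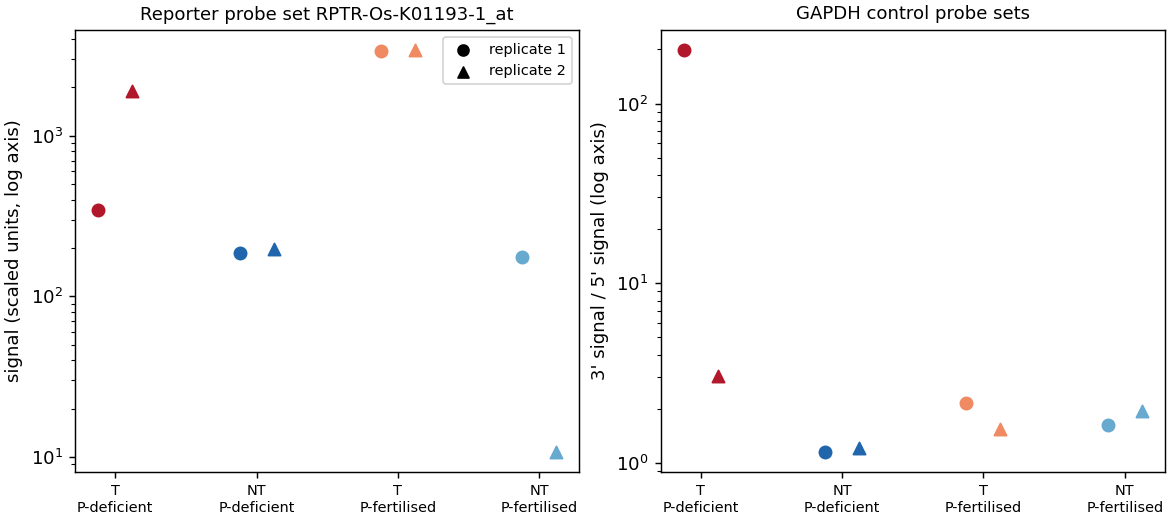
Signal of the reporter probe set RPTR-Os-K01193-1_at (left, log axis) and the GAPDH 3-prime to 5-prime signal ratio (right, log axis) per array, in the 4 groups of genotype and soil, with circles for replicate 1 and triangles for replicate 2. The 4 T arrays read 345.3 to 3393.7 on the reporter, above the highest NT array at 198, and the ratio reached 198 on T replicate 1 in P-deficient soil.

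In P-deficient soil a probe set of BURP2 (LOC4338119), a gene of the BURP-domain family, rose in T by 3.33 ± 0.28 (log2, SE). It read 77.6 ± 8.49 in NT and 1073 ± 188 in T (SD, n = 2 arrays each, limma adjusted p = 0.00946). A probe set of the glycolytic aldolase gene AldC-1 (LOC4325027) fell by 4.67 ± 0.35, from 2565 ± 896 to 72.25 ± 46.3 (limma adjusted p = 0.00646). The other probe set of AldC-1 read 3539 and 3840.9 in T and 3257.7 and 5079.6 in NT. A probe set of PAL (LOC4330034), for phenylalanine ammonia-lyase at the entry to phenylpropanoid synthesis, fell by 3.61 ± 0.29 (adjusted p = 0.00677). That of CAT-B (LOC4342124), a catalase gene, fell by 3.02 ± 0.34 (adjusted p = 0.0294). That of HAK7 (LOC4344235), for a potassium transporter, fell by 2.35 ± 0.23 (adjusted p = 0.0139). That of CPK13, for a calcium-dependent protein kinase, fell by 2.02 ± 0.18 (adjusted p = 0.0112).

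These falls were seen by 1 probe set per gene. The other probe sets of the same genes had median T minus NT differences of -0.14 (AldC-1), -0.13 (PAL), 0.26 (CAT-B), -0.05 (HAK7) and -0.13 (CPK13), and that of BURP2 read 0.74. The T arrays concerned had GAPDH 3-prime to 5-prime ratios of 198 and 3.05, against 1.15 and 1.21 on the NT arrays. Of 34316 probe sets 37 passed, 4 higher and 33 lower in T, and 4551 had an unadjusted p under 0.05. Chosen after their values were seen, the largest fall was that of LOC4338208 at -6.56 ± 0.43 (adjusted p = 0.00646), whose other probe set differed by -0.2. The other 3 higher probe sets, also chosen afterwards, were LOC4347210 at 0.99 and 2 without a listed gene, which read 83.55 in T and 15.65 in NT, and 120.5 in T and 22.05 in NT. By the rule for named genes, EXPB6 (a beta-expansin, 0.96, adjusted p = 0.158), HSP23.2 (a small heat shock protein, 0.88, adjusted p = 0.16), ADIPOR1 (0.72, adjusted p = 0.17) and OsRac7 (a small GTPase, 0.65, adjusted p = 0.172) came next among the higher genes and did not pass in limma.

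The number passing in P-deficient soil changed with single arrays. It was 15 without T replicate 1, 504 without T replicate 2 and 8 without NT replicate 2 of that soil, 10 without either NT array of P-fertilised soil in turn, 13 with no filter, 10 on the 4 arrays of that soil alone and 0 with the GAPDH ratio as a covariate. Without NT replicate 2 the adjusted p was 0.0504 for AldC-1 and HAK7, 0.0553 for BURP2, 0.054 for PAL, 0.0606 for CAT-B and 0.0522 for CPK13. Without T replicate 1 it was 0.0726 for CPK13, 0.0934 for HAK7 and 0.2 for CAT-B, while EXPB6 reached 0.0375 without T replicate 2. CAT-B also passed the threshold no longer without NT replicate 1 (0.0584) or without NT replicate 1 (0.0847) or 2 (0.0854) of P-fertilised soil, and neither did HAK7 without these last arrays (0.0523 and 0.0526). With the covariate the 6 genes no longer passed in limma (adjusted p-values between 0.199 and 0.651), with larger errors and residual degrees of freedom of 3 in place of 4. Their differences stayed large, which does not speak against poorer RNA integrity. The ratio differed within groups mainly between T replicates 1 and 2 of P-deficient soil, so a loss shared by both could not be removed. BURP2 was 3.60 ± 0.41, AldC-1 -3.96 ± 0.39, PAL -3.11 ± 0.35, CAT-B -2.70 ± 0.50, HAK7 -2.03 ± 0.30 and CPK13 -1.99 ± 0.27. Of 17 alternatives CAT-B missed the threshold under 9, HAK7 under 6, CPK13 under 3 and BURP2, AldC-1 and PAL under 2 each. Among these were no filter for CAT-B (limma adjusted p = 0.1) and HAK7 (0.0534) and the replicate block for CAT-B (0.0908).

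**Figure D2:**
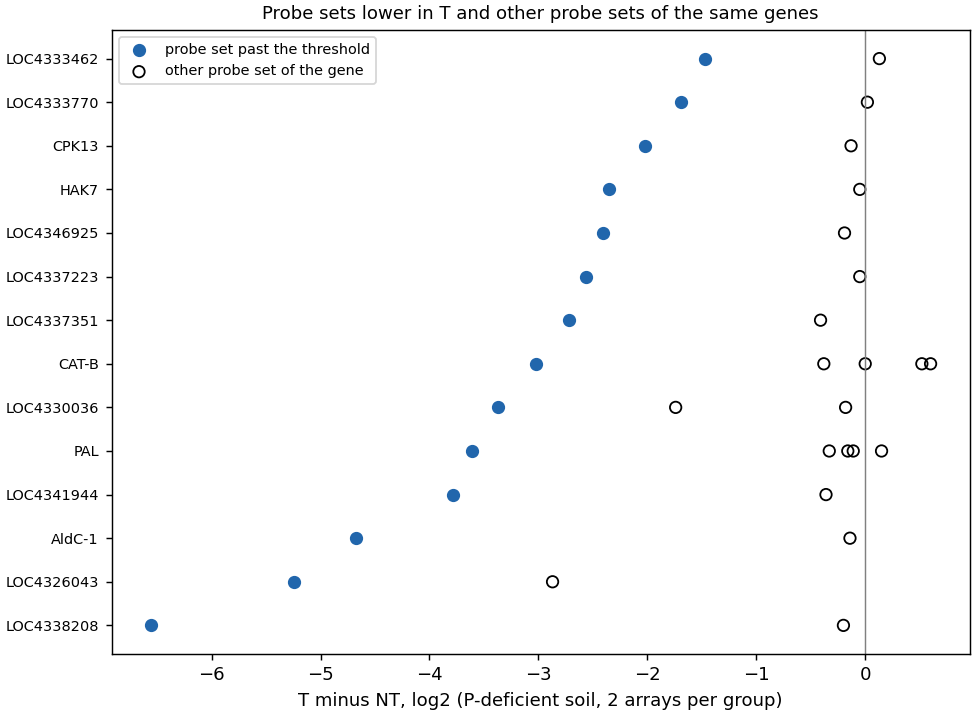
T minus NT log2 difference in P-deficient soil for the 14 genes that had a probe set past the threshold and lower in T and another tested probe set, with filled points for the probe set past the threshold and open points for the others. The filled points had a median of -2.87 and the 21 open points a median of -0.14.

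The phosphate genes named here did not pass singly between the genotypes over all probe sets. The SPX genes code for sensors of phosphate status, and over both soils SPX1 differed by 0.04 ± 0.22 (limma adjusted p = 0.967), SPX2 by 0.32 ± 0.14 (0.521) and SPX3 by 0.02 ± 0.18 (0.976). Among transporters that take up phosphate, the difference was 0.15 for OsPT2, 0.09 for OsPT4, 0.05 for OsPT8 and -0.64 ± 0.22 for OsPT6 (adjusted p = 0.464), and for PHO1-2, which loads phosphate into the xylem, it was -0.24 ± 0.12 (adjusted p = 0.546), and -0.54 ± 0.16 in P-deficient soil (adjusted p = 0.264). In P-deficient soil OsPT6 read 125.8 ± 59.3 in T and 306 ± 115 in NT (n = 2 arrays each, -1.11 ± 0.32, limma adjusted p = 0.245). HOX1, a homeobox gene in the list of root initiation regulators, read 1107 ± 80.4 in T and 690 ± 10.9 in NT in P-deficient soil (0.66 ± 0.15, limma adjusted p = 0.179, n = 2 arrays each), and WOX11, a regulator of crown root emergence, differed by 0.13 over both soils (adjusted p = 0.74). CSLD1, needed for root hair growth and the single member of its list, differed by 0.22 (adjusted p = 0.556).

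As groups, genes of diterpenoid phytoalexin synthesis, whose products are antimicrobial, and phosphate transporters were shifted down in T in P-deficient soil by camera. In the phytoalexin list 0 of 15 genes passed singly over all genes or adjusted over the list alone, with a median of -0.49, and camera gave an adjusted p of 4.28e-05 (adjusted p = 0.561 with an estimated correlation). Its members with the smallest p were KSL4 (-0.72 ± 0.22), CYP99A3 (-0.83 ± 0.30), KSL10 (-0.73 ± 0.27) and KSL7 (-0.47 ± 0.18). Of the 10 phosphate transporters 0 passed over all genes and 3 were lower when adjusted over the list alone, OsPT3 (-0.90), OsPT6 (-1.11) and PHO1-2 (-0.54), with a median of -0.24 and a camera adjusted p of 0.00665 (adjusted p = 0.561 with an estimated correlation). Both lists were compared on T arrays with GAPDH ratios of 198 and 3.05. Without NT replicate 2 of P-deficient soil neither list passed (0.162 and 0.54) and the medians were -0.15 and -0.08, and the transporters also missed the threshold with the lowest 60 percent of probe sets left out (0.0633) and with the GAPDH covariate (0.0908).

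In P-fertilised soil 1 probe set passed, for LOC4326189, a gene without a name that was chosen after its values were seen. It rose in T by 2.57 ± 0.18, from 7.35 ± 4.88 in NT to 201.6 ± 2.05 (SD, n = 2 arrays each, limma adjusted p = 0.0147), and read 144.8 in T and 86.65 in NT in P-deficient soil. In limma 897 probe sets had an unadjusted p under 0.05. By the rule for named genes, those with the smallest p did not pass, each with a limma adjusted p of 1. On the higher side they were ALDP (0.49), SPX5 (0.96), D3 (0.54), GER5 (1.71) and PETE (2.20), the gene of the photosynthetic electron carrier plastocyanin. On the lower side they were ADC1 (-0.80), the auxin efflux carrier gene PIN4 (-1.10), CPK13 (-0.69), the cellulose synthase gene CESA1 (-0.95) and SRP14 (-0.56). PETE read 72.4 and 367.7 and GER5 55.6 and 281.5 on the T arrays, the higher value on replicate 2 in both, and GER5 had an adjusted p of 0.0476 without T replicate 1. LOC4326189 no longer passed without T replicate 2 of that soil, where 3 other probe sets passed, all lower in T, without NT replicate 2, where 1 other passed, lower in T, or without NT replicate 1, where 0 passed. The count was 7, all higher, without T replicate 1, and 0 with a pseudocount of 1, with no filter or on the 4 arrays of that soil alone.

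Genes of photosynthesis, listed as markers of green tissue, were shifted up in T in P-fertilised soil, and cytosolic ribosomal protein genes were shifted down. In the photosynthesis list 0 of 11 genes passed over all genes and 3 were higher when adjusted over the list alone, with a median of 0.37 (camera adjusted p = 2.34e-06, and adjusted p = 0.83 with an estimated correlation). CAB2R, for a chlorophyll-binding protein, read 66.3 and 397.3 on the T arrays and 27.2 and 19.7 on the NT arrays. Without T replicate 2 the list's adjusted p was 0.0738 and its median 0.13. In the ribosomal list 0 of 22 genes passed, over all genes or adjusted over the list alone, with a median of -0.15 (camera adjusted p = 2.34e-06, and adjusted p = 0.83 with an estimated correlation), among them RPL39C (-0.32), RPL5 (-0.23), RPL9 (-0.22) and RPS3A (-0.22). With quantile normalization this list missed the threshold (0.0806).

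Over both soils, a probe set of CPK13 fell in T by 1.36 ± 0.13 and that of AldC-1 by 2.54 ± 0.25. That of PAL, whose arrays overlapped between genotypes in P-fertilised soil, fell by 1.99 ± 0.20 (limma adjusted p = 0.0294 for each gene). For AldC-1 and PAL most of this came from P-deficient soil (-4.67 and -3.61), as T read 2477 and 1062 and NT 3238 and 1342 in P-fertilised soil. The other probe sets of these genes had median differences of -0.14 (CPK13), -0.09 (AldC-1) and -0.07 (PAL). In all 11 probe sets passed, 2 higher and 9 lower, with 3303 at an unadjusted p under 0.05, and 9 of the 11 also passed in P-deficient soil. Chosen after their values were seen, the 2 higher were LOC4326189 (1.58 ± 0.13) and a probe set without a listed gene (1.25 ± 0.11). Named genes that did not pass were, on the higher side, BURP2 (1.41, adjusted p = 0.106), HOX1 (0.55, 0.228), ADIPOR1 (0.53, 0.254), OsSAP9 (0.45, 0.303) and HOX4 (0.48, 0.35), and on the lower side ADC1 (-0.91, 0.0552) and HAK7 (-1.36, 0.0574). Here too the GAPDH ratio reached 198 and 3.05 on 2 of the 4 T arrays. The count was 0 without T replicate 1 of P-deficient soil, without either NT array of that soil or without NT replicate 1 of P-fertilised soil, 1 without NT replicate 2, 5 without T replicate 1 and 23 without T replicate 2 of P-fertilised soil, and 236 without T replicate 2 of P-deficient soil, where ADC1 (0.0339) and HAK7 (0.018) passed. It was also 0 with a pseudocount of 1, no filter, the replicate block, the GAPDH covariate or an additive term for soil. AldC-1, CPK13 and PAL missed the threshold under 10, 10 and 12 of 17 alternatives, with adjusted p-values of up to 0.205.

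Camera placed 4 lists lower in T over both soils, with no member past the threshold over all genes. The medians of 3 of them differed in sign between the soils, as the phytoalexin list had 0.22 in P-fertilised against -0.49 in P-deficient soil, phosphate transporters 0.06 against -0.24, and ribosomal proteins -0.15 against 0.04. They were ribosomal proteins (22 genes, median -0.07, adjusted p = 0.00407), phosphate transporters (10 genes, median -0.06), diterpenoid phytoalexin synthesis (15 genes, median -0.14) and jasmonate and ethylene genes (42 genes, median -0.10), the last 3 at an adjusted p of 0.0368. With an estimated correlation each had an adjusted p = 0.753. Adjusted over the list alone, 1 phosphate transporter was lower and 0 genes of the other 3 lists. Members with the smallest p included RPS10 (-0.32) among ribosomal proteins, OsPT3 (-0.63), KSL4 (-0.35), and JAZ6 (-0.36), a repressor of jasmonate signalling. Without NT replicate 2 of P-deficient soil adjusted p-values were 0.662, 0.861, 0.9 and 0.271 in the same order, and the medians 0, 0.06, 0.03 and -0.06, so the direction of the transporters and of the phytoalexin list turned with 1 array. Ribosomal proteins also missed the threshold without T replicate 2 of P-deficient soil (0.074) or NT replicate 2 of P-fertilised soil (0.0602). The transporters and the phytoalexin list did so without T replicate 1 (0.0738 for both) or T replicate 2 of P-deficient soil (0.074 and 0.119) and without T replicate 2 (0.0862 and 0.365) or NT replicate 1 of P-fertilised soil (0.217 and 0.0747), and the phytoalexin list also without NT replicate 2 of P-fertilised soil (0.0602). The jasmonate and ethylene list did so without T replicate 1 of P-deficient soil (0.277) and without T replicate 2 (0.285) or NT replicate 2 (0.114) of P-fertilised soil. The number of lists past the threshold was 5 without NT replicate 1 of P-deficient soil and 7 without T replicate 1 of P-fertilised soil. The GAPDH ratios of 198 and 3.05 apply here too, and with the GAPDH covariate only the ribosomal list of these 4 passed. Quantile normalization ended all 4 (0.0993, 0.063, 0.063 and 0.0938) and no filter or a pseudocount of 1 all but the ribosomal list.

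Whether the genotype effect differed between soils was asked with the interaction. Limma placed 0 probe sets past the threshold, with 2032 at an unadjusted p under 0.05. BURP2 had the smallest p among the named genes, with a difference of effects of 3.83 ± 0.40 (adjusted p = 0.123), as T minus NT was 3.33 in P-deficient and -0.50 in P-fertilised soil. The next were SRP14 (1.22), OsRac7 (0.86), HSP23.2 (0.93) and S1FA (0.77) on the positive side and AldC-1 (-4.26, adjusted p = 0.153), PAL (-3.23, 0.187), HAK7 (-1.98, 0.402), CPK13 (-1.32, 0.667) and CAT-B (-2.41, 0.667) on the negative side. Without T replicate 2 of P-deficient soil 140 probe sets passed, BURP2 (0.0316), AldC-1 (0.0166) and PAL (0.0268) among them, and BURP2 also did without NT replicate 2 of P-fertilised soil (0.0233), where 2 passed. The count was 4 without T replicate 1 and 1 without T replicate 2 of P-fertilised soil. The GAPDH ratios of 198 and 3.05 on the T arrays of P-deficient soil enter every value of this test. Across 34316 probe sets, the T minus NT differences of both soils, which share no array, correlated at a Pearson r of 0.24 and a Spearman rho of 0.19, and 56.4% had the same sign. The Pearson r was 0.15 without T replicate 1 and 0.16 without NT replicate 1 of P-fertilised soil.

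The soils differed far more than the genotypes. Among the named genes higher in P-deficient soil at heading were the dehydrin genes RAB16B at 6.13 ± 0.32 (log2, SE, limma adjusted p = 2.2e-06), RAB21 at 4.84 ± 0.91 (0.00251) and RAB16D at 4.69 ± 0.75 (0.00105). RAB16B read 4215 ± 1.56 in T and 4938 ± 1340 in NT, against 31.1 ± 28.7 and 46.45 ± 47.7 in P-fertilised soil (SD, n = 2 arrays each). The small heat shock protein gene HSP18.6 rose by 6.12 ± 0.15, the sugar transporter gene SWEET12 by 6.10 ± 0.11 and the pyruvate dehydrogenase gene PDHE1-A by 5.82 ± 0.18. Further rises were those of rDRP1 (5.74), ELA3 (5.52), the peroxiredoxin gene R1C-Prx (5.21), OsPM19L1 (from 116.2 to 4719 in T), the protein phosphatase gene OsPP2C59 (4.90) and OsNrx2 (4.79). The 2 other probe sets of HSP18.6 had a median of 2.63.

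Among the named genes lower in that soil PRX74, a secreted peroxidase gene, fell by 5.79 ± 0.28 (limma adjusted p = 1.66e-06), from 2269 ± 39 in T and 2568 ± 109 in NT in P-fertilised soil to 32.5 ± 43.6 and 2.65 ± 3.04 (SD, n = 2 arrays each). The beta-expansin genes EXPB2, EXPB6 and EXPB7, whose products loosen cell walls, changed by -5.26, -4.87 and -4.54. The silicon efflux transporter gene Lsi2 fell by 4.78 ± 0.25, the nicotianamine synthase gene NAS1, which makes a chelator of iron, by 4.69 ± 0.26, and the copper transporter gene COPT1 by 4.63 ± 0.13. CPDK2 (-5.03), OsCASPL1U3 (-4.83), the sugar transporter gene SWEET1A (-4.53), the auxin conjugate hydrolase gene ILL3 (-4.52) and the haemoglobin gene NSHB1 (-4.48 ± 0.45) fell too, and the other probe set of SWEET1A differed by -0.84.

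Of 34316 probe sets 16170 passed in limma, 7649 higher and 8521 lower in P-deficient soil, 5516 of them by over 2-fold, and 18571 had an unadjusted p under 0.05. The median difference of all probe sets was 0.009, and with median centring it was 0.165 and the split 11983 higher and 6633 lower, so the balance of directions depended on the scaling. The GAPDH ratio of the T arrays in P-deficient soil (198 and 3.05) lay apart from the rest. Without both of these arrays, a choice made after seeing the data, the comparison in NT alone gave 11106.

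Genes of phosphate supply moved in both directions between the soils. SPX3 rose by 3.12 ± 0.18 (limma adjusted p = 3.95e-06), from 21.95 ± 7.71 in T and 22.05 ± 4.74 in NT to 458.7 ± 161 and 433.5 ± 101 in P-deficient soil (SD, n = 2 arrays each). SPX5 rose by 2.63 ± 0.16, SPX2 by 1.85 ± 0.14 and SPX1 by 1.04 ± 0.22 (adjusted p = 0.00432), while LPR4 fell by 1.51 ± 0.13. Of 10 genes of P starvation signalling 5 rose and 3 fell, both over all genes and adjusted over the list alone, with a median of 0.59 (camera adjusted p = 0.4). Among phosphate transporters OsPT4 rose by 1.81 ± 0.12, OsPT6 by 1.58 ± 0.22 and OsPT8 by 0.78 ± 0.19 (limma adjusted p = 0.00855), whereas OsPT2 fell by 2.13 ± 0.21. PHO1-2 fell by 2.57 ± 0.12 on the probe set used, while its 2 other probe sets had a median of only -0.37. Of the 10 phosphate transporters 3 rose and 2 fell (the same numbers adjusted over the list alone), and camera gave an adjusted p of 0.835. In the list of lipid remodelling genes, meant to hold those that spare phosphate in membranes, 4 of 5 rose, also adjusted over the list alone (MGD2 1.63, PLD1 0.72, MGD3 0.47 and PLD2 0.42), at a camera adjusted p of 0.128. PLD1 and PLD2 were matched by name, and whether they are of the phospholipase D zeta class fixed for the list was not checked. OsPT11, a transporter of mycorrhizal roots and the single gene of its list, differed by 0.92 ± 0.65 and did not pass (adjusted p = 0.279). HOX1 rose by 1.90 ± 0.11 and CSLD1 fell by 0.49 ± 0.11, and WOX11 at -0.32 did not pass (adjusted p = 0.0532).

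**Figure D3:**
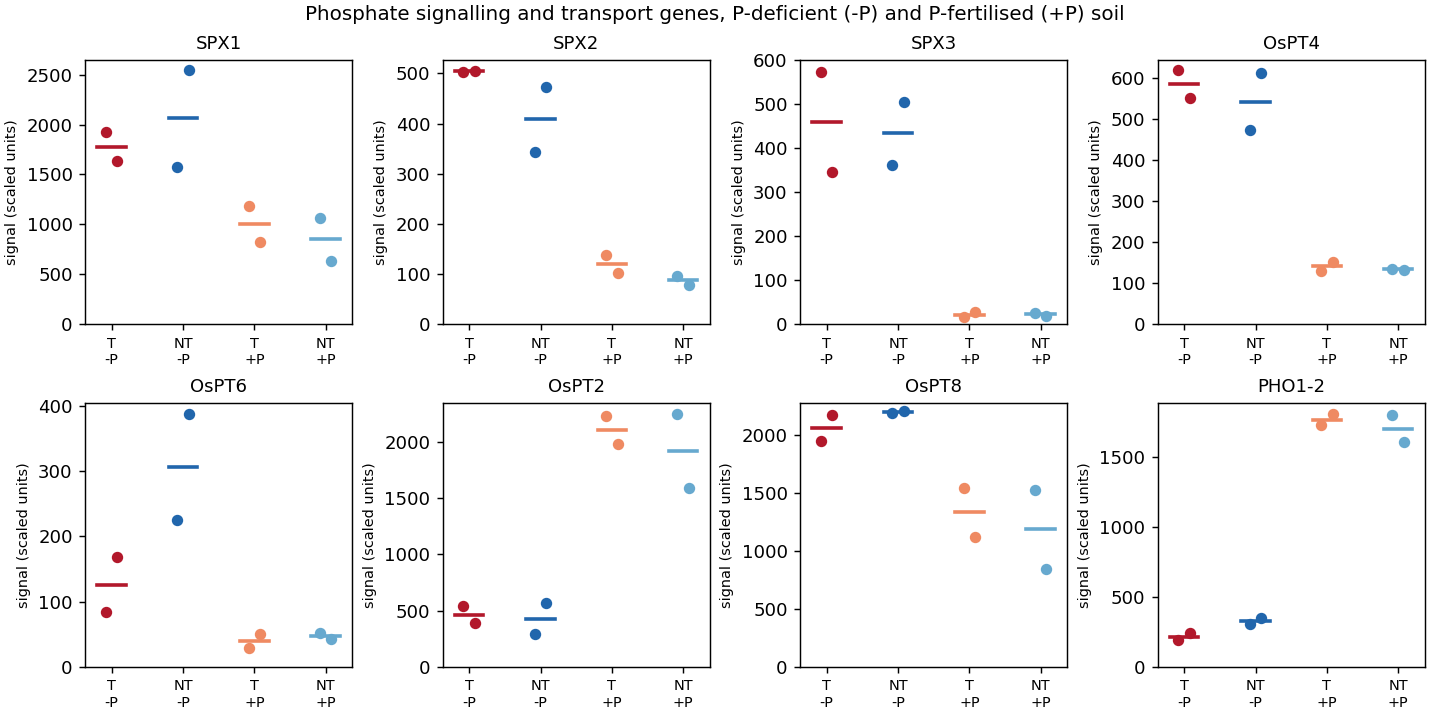
Signal (intensity) of SPX1, SPX2, SPX3, OsPT4, OsPT6, OsPT2, OsPT8 and PHO1-2 in the 4 groups, with points for arrays and bars for group means. SPX3 means were 458.7 and 433.5 in P-deficient and 21.95 and 22.05 in P-fertilised soil, and OsPT2 means 462.4 and 428.8 against 2108 and 1923.

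The lists of cell division genes, of expansins and of cellulose synthases were shifted down in P-deficient soil by camera at its preset correlation. Of 84 genes of cell division and histones 57 fell and 4 rose (57 and 6 adjusted over the list alone), with a median of -1.04, the mitotic cyclin CYCB1-1 at -3.04 ± 0.16 and the kinesin KIN12C at -2.18 ± 0.11 among them (camera adjusted p = 1.54e-07, and adjusted p = 0.411 with an estimated correlation). Of 26 expansins and xyloglucan enzymes 20 fell and 1 rose (20 and 2 adjusted over the list alone), with a median of -1.74, EXPA1 at -3.38 ± 0.13 (camera adjusted p = 5.08e-06, and adjusted p = 0.301 with an estimated correlation). Cellulose synthase family genes fell in 17 of 28 cases and rose in 4, also adjusted over the list alone, with a median of -0.91 (0.00733, and adjusted p = 0.441 with an estimated correlation). CSLC3 changed by -2.88, CSLA1 by -2.78 and the secondary wall gene CESA7 by -2.38, and CSLA5 rose by 3.33. Under median centring 53 cell division genes, 19 expansins and 16 cellulose synthases were lower and 10, 2 and 5 higher.

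The lists of iron acquisition and of aquaporins were shifted down too. Of 25 iron acquisition genes 17 fell and 1 rose, also adjusted over the list alone, with a median of -1.25, NAS2 at -3.75 ± 0.21, the metal transporter gene Nramp1 at -3.04 ± 0.16 and YSL15, for uptake of iron chelates, at -2.48 ± 0.11 (camera adjusted p = 0.000466, and adjusted p = 0.411 with an estimated correlation). IRT1, an iron transporter gene, fell by 1.25 ± 0.14. Of 23 aquaporins, which are water and solute channels, 14 fell and 2 rose, also adjusted over the list alone, with a median of -0.60. The silicon channel gene NIP2-2 changed by -3.91, PIP2-4 by -2.74 and PIP2-2 by -2.62, and the seed vacuole aquaporin gene TIP3-1 rose by 3.45. Camera gave the aquaporins an adjusted p of 0.0345 (adjusted p = 0.441 with an estimated correlation), and 0.0634 without NT replicate 1 of P-deficient soil.

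Genes of diterpenoid phytoalexin synthesis, heat shock and starch were shifted up in P-deficient soil. Of 15 phytoalexin genes 13 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 1.45e-05, and adjusted p = 0.411 with an estimated correlation). The diterpene cyclase gene CPS2 rose by 3.77 ± 0.25 and the cytochrome P450 gene CYP701A8 by 3.75 ± 0.16, followed by CPS4 (2.90 ± 0.22) and KSL7 (2.69 ± 0.13). Of 50 heat shock genes 28 rose and 9 fell (30 and 10 adjusted over the list alone), with a median of 0.52, HSP16.9A at 4.54, HSP18.0 at 4.31 and HSF05, a heat shock factor gene, at 3.17 (camera adjusted p = 0.000466, and adjusted p = 0.301 with an estimated correlation). Under median centring 14 phytoalexin genes and 33 heat shock genes were higher. Of 9 starch genes 3 rose and 0 fell, also adjusted over the list alone (SS1 2.63, Rbe1 1.80 and AGPS2 1.44), at a camera adjusted p of 0.0393 (adjusted p = 0.411 with an estimated correlation). The starch list missed the threshold without T replicate 2 of either soil (0.0607 in P-deficient and 0.057 in P-fertilised soil), with no filter (0.0522) and with the lowest 60 percent left out (0.0642).

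**Figure D4:**
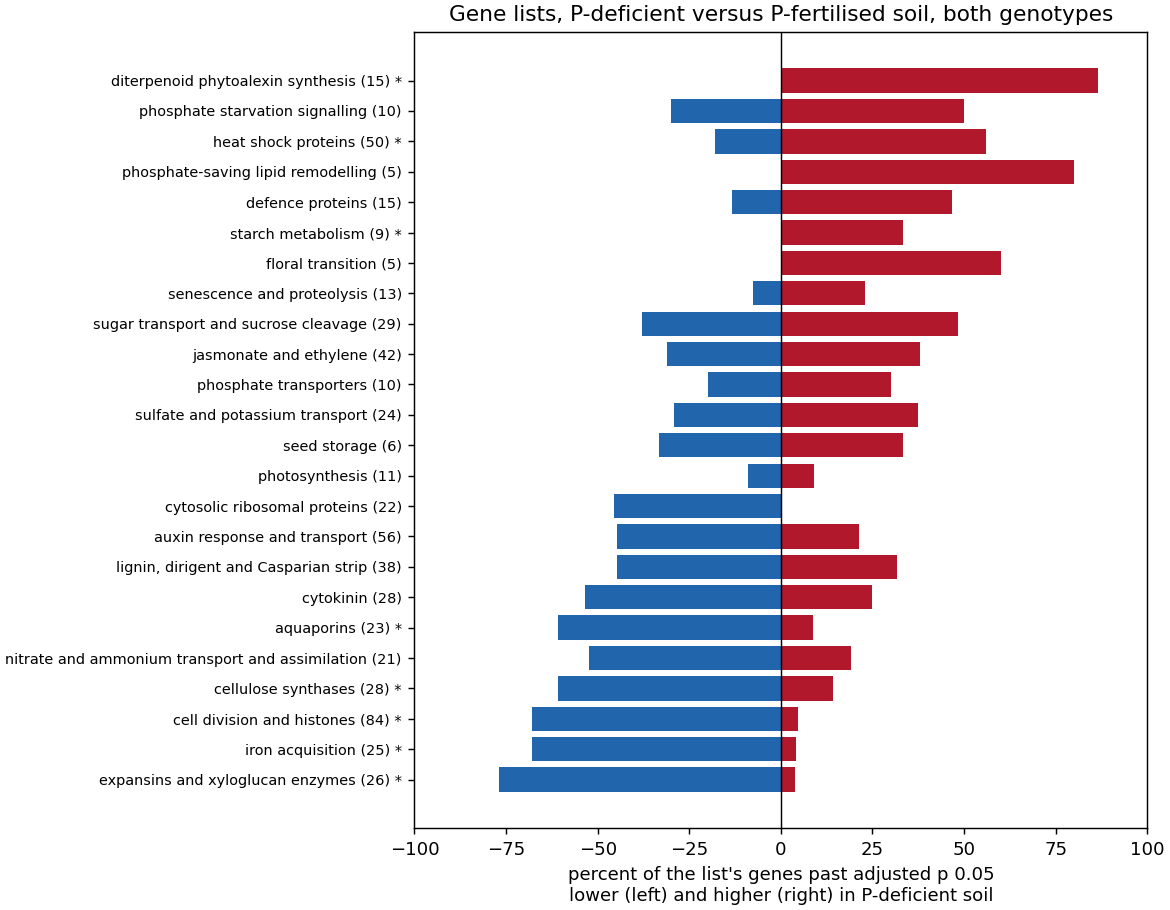
Percent of the genes of each of 24 lists past the threshold and lower (blue, left) or higher (red, right) in P-deficient than in P-fertilised soil, over both genotypes, with list sizes in brackets and stars at lists past the camera threshold. Of 84 cell division genes 57 were lower and of 15 phytoalexin genes 13 higher, and only the photosynthesis list had a median whose sign turned with the scaling (-0.10, and 0.07 with quantile normalization).

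The other lists did not pass in camera, though members of most did in limma. Sugar transport and sucrose cleavage genes rose in 14 and fell in 11 of 29 cases, with SWEET12 at 6.10, the sucrose synthase gene SUS4 at 4.63, SWEET15 at 2.76 and the invertase gene CIN7 at -2.77 (adjusted p = 0.584). Nitrate and ammonium genes fell in 11 and rose in 4 of 21 cases (12 and 6 adjusted over the list alone), with the glutamine synthetase genes GLN1-2 at -3.26, GLN2 at -2.40 and GLN1-1 at -2.38 (0.157). Sulfate and potassium transport genes rose in 9 and fell in 7 of 24 cases, with HAK16 at 2.93, KCO2 at 2.49 and AKT1 at -1.71 (0.59). Lignin and Casparian strip genes fell in 17 and rose in 12 of 38 cases (21 and 13 adjusted over the list alone), with OsCASP1 at -3.54 and the laccase gene LAC3 at -3.42 (0.179). Auxin genes fell in 25 and rose in 12 of 56 cases (27 and 13 adjusted over the list alone), with IAA30 at -3.68 and PIN6 at -2.16 (0.157). Cytokinin genes fell in 15 and rose in 7 of 28 cases (15 and 8 adjusted over the list alone), with the cytokinin-activating LOGL1 at -2.45 (0.185). Where no count is given, those adjusted over the list alone were the same.

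Jasmonate and ethylene genes rose in 16 and fell in 13 of 42 cases, with a median of 0.09, a mean of -0.13 and LOX1.1 at -2.94 (camera adjusted p = 0.849). Defence genes rose in 7 and fell in 2 of 15 cases, with the chitinase gene Cht1 at 2.17 and Rcb4 at -2.66 (0.157). Ribosomal protein genes fell in 10 of 22 cases and rose in 0, with RPL11 at -0.82 (0.0698). Senescence genes rose in 3 and fell in 1 of 13 cases, with OSL2 at 1.88 and the chlorophyll breakdown gene SGR at 0.85 (0.557). Seed storage genes rose in 2 and fell in 2 of 6 cases, with RA14 at 1.16 and GLB1 at -1.02 (0.835). Markers of the floral transition rose in 3 of 5 cases and fell in 0, with the MADS-box genes MADS18 at 1.61, MADS14 at 0.86 and MADS15 at 0.33 (0.17). Of 11 photosynthesis genes 1 rose and 1 fell (0 and 1 adjusted over the list alone), at a camera adjusted p of 0.835 and a median of -0.10 that turned to 0.07 with quantile normalization and 0.05 with median centring. The list of class III peroxidases held 4 genes, too few for camera. Of these PRX74, PRX112 (-4.26) and 1 named peroxidase (-2.34) fell, and R1C-Prx, by its name a peroxiredoxin, rose. The lists of purple acid phosphatases and of receptor kinases related to PSTOL1 matched 0 genes. With an estimated correlation 0 of the 24 lists passed in camera, while fry, which does not set a list against other genes, placed 21 past the threshold. As 47.12% of all probe sets passed between the soils, the 21 do not set these lists apart from other genes. For T against NT, over both soils or in each, and for the interaction, fry placed 0 lists past the threshold.

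Each genotype showed the soil difference on its own. Among genes with a name and chosen by the rule, RAB16B, SWEET12, HSP18.6, PDHE1-A and ELA3 rose most in NT (6.11, 5.93, 5.83, 5.76 and 5.54), and HSP18.6, SWEET12, RAB16B, rDRP1 and PDHE1-A in T (6.40, 6.27, 6.15, 5.94 and 5.89). The deepest falls among them were those of PRX74, EXPB2, the vacuolar aquaporin gene TIP2-1, EXPB6 and NAS1 in NT (-6.23, -5.61, -5.39, -5.35 and -4.98) and of PRX74, CPDK2, EXPB2, NSHB1 and Lsi2 in T (-5.34, -5.16, -4.90, -4.87 and -4.86). Over the alternatives the rise in NT ran from 4.43 to 8.12 for HSP18.6 and from 5.12 to 7.18 for RAB16B, so the order of the rises depended on the setting. In NT 11166 probe sets passed in limma (5303 higher and 5863 lower), and in T 12235 (5304 and 6931). Camera placed 9 lists past the threshold in NT and 6 in T at its preset correlation, and 0 in each with an estimated correlation. Both genotypes shared 3852 higher and 5039 lower probe sets, where independent lists of these sizes would share 820 and 1184, and 16 went opposite ways, and across probe sets the log2 differences of NT and T correlated at 0.92. Median centring turned the splits to 7037 higher and 5050 lower in NT and 9005 and 4975 in T. The NT count was 7234 without NT replicate 1 and 6821 without NT replicate 2 of P-fertilised soil, and the T count 7855 without T replicate 2 of P-fertilised soil.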

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

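The sibling probe sets, the P-fertilised values and the covariate used for the integrity of the RNA were looked at only after the GAPDH ratios had been seen, except that the outcome of the sibling and quantile tests was written down before these were run. The GAPDH 3-prime to 5-prime ratio was 198 on T replicate 1 and 3.05 on T replicate 2 of P-deficient soil, against 1.15 and 1.21 on the NT arrays of that soil. Of 33 probe sets lower in T there, 16 had 1 gene, and 14 of these genes had 21 other probe sets, with a median T minus NT difference of -0.14 (-0.2 to -0.05, bootstrap over the probe sets) against -2.87 for the called probe sets. Exceptions, chosen after their values were seen, were another probe set of LOC4326043 at -2.87 (adjusted p = 0.059) and 1 of 2 others of LOC4330036 at -1.74 (adjusted p = 0.22), which this reading leaves unexplained. AldC-1, PAL, CAT-B, HAK7 and CPK13 may have been read as lower through poorer 5-prime coverage of the T arrays. The positions of the probe sets on their transcripts were not looked up, so which of them read the 5-prime end is not known. The called probe sets were also picked for their large falls and the others were not. The smaller differences of the others therefore cannot decide whether 5-prime coverage was the cause. Of the 21 others, 17 lay between -0.5 and 0.5, and their median signal was high (2858 over all 21). For genes other than LOC4326043 and LOC4330036, this argues against a fall of the whole transcript as large as on the called probe set. A genotype effect shared by both soils was also weighed. The same 33 probe sets had a median of -0.34 (-0.41 to -0.23) in P-fertilised soil, 29 of them lower, which left that reading undecided. The bootstrap ranges are over probe sets of the same arrays and do not measure the spread between arrays. With the GAPDH covariate the median of the 33 went from -2.2 ± 0.24 to -1.79 ± 0.27. Residual degrees of freedom went from 4 to 3 and the count from 37 to 0. Within groups the ratio differed most between the T arrays of P-deficient soil (198 and 3.05), so its fitted effect rests mainly on them. The covariate could not remove a loss of 5-prime signal shared by both T arrays, so the difference that remained does not speak against such a loss.

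Leaving out T replicate 2 of P-fertilised soil was chosen as a test of the photosynthesis list only after that array's values had been seen. CAB2R read 397.3 on that array and 6 to 67.1 on the others, PETE 367.7 against 4.9 to 102.2, and 9 of 15 probe sets of these genes were highest there. OsrbcS, for the small subunit of Rubisco, read 108.8 there on the probe set used in the list (84.6 to 116.7 on the others) and 250.9 on another probe set (25.3 to 86.2 on the others). Green tissue RNA in 1 T array may or may not account for the list's rise, as the array was picked from these same values and OsrbcS did not rise on both probe sets. The list's adjusted p was 2.34e-06 with all arrays and 0.0738 without this array, within a range of 8.85e-15 to 0.0738 over 17 alternatives. Between-array scaling by the authors would have been met by a loss under quantile normalization, where the adjusted p was 7.26e-06.

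The T minus NT effect on 3 lists differed between the soils in camera, each at an adjusted p = 0.553 with an estimated correlation and with 0 members past the threshold. Phosphate transporters had an interaction median of -0.36 and an adjusted p of 0.0132, within a range of 0.000375 to 0.627, and missed the threshold without NT replicate 2 of P-deficient soil (0.627), without NT replicate 2 of P-fertilised soil (0.168), with the lowest 60 percent left out (0.0567) and with the GAPDH covariate (0.0755). Diterpenoid phytoalexin synthesis had a median of -0.71 and an adjusted p of 1.57e-06, within a range of 1.21e-09 to 0.00756. Photosynthesis had a median of -0.47 and an adjusted p of 0.000534, within a range of 6.61e-10 to 0.114, and missed the threshold without NT replicate 1 of P-deficient soil (0.114) and with the GAPDH covariate (0.0755).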

How the results depend on the processing

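Counts past the threshold were set beside alternatives, of which the GAPDH covariate, the crossed pairing and the additive terms were added after the data were seen. T versus NT, both soils (11), became 0 with a pseudocount of 1, no filter, the replicate block, the GAPDH 3-prime to 5-prime covariate or soil as an additive term, and 0 to 236 with arrays left out in turn. T versus NT, P-deficient soil (37), became 13 with no filter, 19 with the replicate block, 10 on only the 4 arrays of that soil, 0 with the covariate, and 8 to 504 with arrays left out. T versus NT, P-fertilised soil (1), became 0 with a pseudocount of 1, no filter, the replicate block or only the 4 arrays of that soil, and 0 to 7 with arrays left out. The labels give the replicate numbers no shared batch or plant, and differences between replicates correlated at -0.26 between T and NT in P-deficient and 0.21 in P-fertilised soil, so the numbers were not taken as pairs and shared handling in P-fertilised soil was not excluded. A crossed replicate block in P-deficient soil gave 19 over both soils and 81 in P-deficient soil. The genotype by soil interaction (0) gave 0 to 140 with arrays left out. P-deficient versus P-fertilised, NT, gave 6821 to 11111 and P-deficient versus P-fertilised, T, 7855 to 13865. Gene lists, T versus NT, both soils (4), became 1 with a pseudocount of 1 or no filter, 0 with quantile normalization, 2 with the covariate, 0 with the correlation estimated per list, and 0 to 7 with arrays left out. Those in P-deficient soil (2) became 4 with a pseudocount of 100 or median centring, 1 with the covariate, 0 with the correlation estimated per list, and 0 to 4 with arrays left out. Those in P-fertilised soil (2) became 1 with quantile normalization, 0 with the correlation estimated per list, and 2 to 4 with arrays left out, and the 8 soil lists became 0 with the correlation estimated per list. The counts of 236, 504 and 140 were those without T replicate 2 of P-deficient soil, where the T array left had a GAPDH ratio of 198. The cause was not tested for any of these changes. Signal over background limits all of these, since the deposited values hold no detection calls and low signals are compressed by the pseudocount.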

Other observations

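OsPT11, a phosphate transporter of roots colonised by mycorrhizal fungi, differed between replicates of every group. It read 932.6 and 438.5 in T and 388.5 and 1434.4 in NT in P-deficient soil, and 713.5 and 121.4 in T and 859.1 and 179.5 in NT in P-fertilised soil, which are fold differences of 2.13, 3.69, 5.88 and 4.79 within the pairs. Another probe set of this gene differed in the same direction in 3 pairs, at 109.2 and 205.4 in NT in P-deficient soil and at 247.5 and 8.1 in T and 163.7 and 32.2 in NT in P-fertilised soil, and in the other direction in T in P-deficient soil, at low signals of 0.8 and 12.2.

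Both tests of OsPT11 were chosen only after its values per array had been seen. Roots colonised to different degrees might differ in this way, through a response shared by many genes. Of the probe sets that differed at least 2-fold in all 4 pairs, 1 had the sign pattern of OsPT11, namely OsPT11 itself, and the highest other of the 8 patterns had 2, which are too few to decide. Chosen after its values were seen, RAB21 read 234.1 and 1.7 in T and 706.4 and 9.4 in NT in P-fertilised soil, in the same direction as OsPT11. In P-deficient soil it read 3196.6 and 5856.3 in NT, also in that direction, and 3011.4 and 3173.6 in T, in the other direction. RAB21 was not alone, as in P-fertilised soil RAB16D read 420 and 40.4 in T and 947.8 and 63 in NT. OsPM19L1 read 190.7 and 41.7 in T and 416.6 and 46.2 in NT there. PRX74 and CPDK2 differed little in that soil and in the other direction, and the named genes were not counted by direction. RNA quality differing between replicates was weighed on the P-fertilised pairs, where the larger fold difference of the GAPDH ratio within a pair was 1.4, which argues against it for those pairs, and the first reading stays open.

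The splits of the 8 arrays into 4 and 4 were counted with the additive model first, after which the model with 4 group means was used because it is the model reported. With soil as an additive term T against NT gave 0 probe sets, and since no split can give fewer, other splits say nothing about that count. With the 4 group means T against NT gave 11, and 4 of 35 splits gave as many. The highest other was the split by soil at 15952, which is the soil difference itself. The other 2, at 23 and 13, contrast arrays within each soil and set T replicate 1 of P-deficient soil alone against the other 3 arrays of that soil, unlike the 2 against 2 of the genotypes. The 35 splits thus do not exclude a grouping by chance, and arms of unequal size make them a poor measure of it. Among 18 balanced splits 1 gave as many, that by genotype itself, with 7 as the highest other, and 18 splits are too few to give a share under 0.05. The soil split gave 16170 probe sets and was 1 of 35 with as many, with 1 as the highest other.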
